A study of Mus musculus with 32 samples.

How the data were processed

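Chromatin accessibility was measured by ATAC-seq, which marks open DNA by transposase insertion, in mouse bone marrow haematopoietic stem and progenitor cells (HSPCs; lineage-negative, cKit-positive, Sca1-positive). The labels list 32 samples, which are 2 technical libraries for each of 16 biological replicates, and 1 peak list per biological replicate was used. Each list was assigned to its group and replicate number by its name. The labels name both the Omni-ATAC protocol and a single-cell Chromium library chemistry, and the lists do not show which was used.

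The authors' processing notes name FastQC, Trim Galore, BWA, Picard and MACS3, without versions, and genome build GRCm38; filters on reads, duplicates or regions are not stated. Each deposited list gives, per peak, the authors' fold enrichment, a ratio of the summit to the background of the same library. It also gives the authors' -log10 p and -log10 q of the peak. These values are the peak's own, are not scaled between libraries, and were used only to rank, filter and describe peaks within a list. The smallest -log10 q in a list was 1.30 to 1.33, a q of 0.05. Pileup and background were recovered from fold and p in 2000 peaks per list, trying whole-number pileups only. In 91.1% to 100% of these peaks, a whole-number summit pileup gave the listed -log10 p to within 0.002. For very strong peaks this limit was wider, in proportion to -log10 p. Among the matched peaks, median summit pileup was 18 to 52 fragments and background pileup 1.53 to 2.64. Total read depth cannot be read from peak lists, and no binomial interval was given. Peaks had a median width of 281 to 594 bp, and the share on chromosome X was 1.77% to 2.11%.

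Lists differed in length, so each was shortened to its 19100 strongest autosomal peaks by -log10 p, the number in the shortest list. Overlapping peaks were merged over all libraries into 31846 regions. The value of a region in a library was the percentile rank of its strongest peak within that library's list. A value of 100 is the strongest peak, and 0 means no peak among the 19100 strongest, which includes peaks the full list holds at a lower rank. The 23554 regions with a peak in at least 3 lists were tested, and 10947 of them had a peak in all 16. Because the value is a rank, a region can move when others do, and differences are in percentile points, not in accessibility.

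One linear model with a mean per group was fitted over all 16 libraries with limma (empirical Bayes, trend and robust options), so that the groups shared 1 estimate of the spread. Contrasts were LPS minus PBS in naive and in AF9-experienced mice, AF9-experienced minus naive after PBS and after LPS, and the difference between both LPS contrasts (interaction). Regions were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. P-values measure the spread between the samples labelled as biological replicates. Single values per library (peak number, gene-end share, median fold) were compared by exact two-sided permutation tests, adjusted over the 4 comparisons of a measure. Similarity was the Jaccard index of equal-length lists, tested by exact permutation of the libraries of both groups.

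The annotation (GRCm38.p6 RefSeq, 21631 protein-coding gene models) gave no strand, so either end of a gene model within 1 kb was called a gene end, in place of a promoter. Regions were linked to the nearest protein-coding gene model within 50 kb. A link is by position and does not show which gene a region acts on. These gene lists were fixed before the data were examined: HSC identity, MLL-AF9 program, granulocyte-monocyte progenitor, neutrophil granule and mature granulocyte, monocyte-macrophage, lymphoid priming, mature T, NK and B lymphocyte, megakaryocyte-erythroid, mast cell and basophil, endothelial and stromal, interferon-stimulated, NF-kB and TLR inflammatory, AP-1 and immediate early, emergency granulopoiesis and IL6-STAT3, antigen presentation, cell cycle, and housekeeping control. All their symbols matched gene models except in the interferon list (42 of 45). Lists were tested against all other linked regions with limma's camera (preset correlation), adjusted over lists within a contrast, and again with an estimated correlation. Limma's fry, which tests whether a list's regions move one way on balance, and an exact permutation test of the share of a list's regions holding a peak stood beside it. A member counted as having risen or fallen by its linked region with the smallest p.

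A rule for the genes named was fixed before the data were examined. It takes the 6 called regions with the smallest adjusted p in each direction, or the 3 with the smallest p where none was called, and up to 4 called members of each list. The rule adds the strongest gene-end region of Ly6a, Irf8, Irf1, Cebpb, Nfkbia, Socs3, Meis1, Hoxa9, Mecom, Gata2 and Flt3, of which Ly6a and Gata2 had none tested. Results at 2 further genes are not reported here, though their regions are in the tests and counts. Chosen after their values were seen were Fosb and Btg2, named beside the other called AP-1 members, and the members named as called when adjusted over the list alone. Motif shares were planned but not analysed here, since they need the genome sequence.

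Alternatives planned before the data were examined were ranking by fold enrichment, 9550 peaks per list, leaving out the 3 shortest lists (59609 peaks per list), 501 bp windows, an overlap of at least 50%, no filter on the number of lists, a log rank, presence or absence in the equal-length or full lists, a -log10 q of at least 5, list length as covariate, the replicate number as a block, library weights, only both groups compared, chromosome X included, gene ends only, and leaving out each replicate. Others were chosen after seeing the data: median fold enrichment as covariate, Y chromosome peaks as covariate, leaving out libraries with Y peaks, keeping only AF9-experienced LPS libraries with Y peaks, leaving out the short lists at 19100 peaks, leaving them out at 59609 peaks with library weights, and full lists for regions seen in 1 treatment alone.

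The region test was tested on simulated data with the residual SD of the real fit (8.85 percentile points; 8.92 to 8.96 simulated) and 100 regions changed by each fold. In the 4 pairwise comparisons it recovered 68% to 76% of regions changed 2-fold on the simulated scale and 68% to 79% of those changed 4-fold. It called 3 to 6 unchanged regions. Of the regions changed 2-fold on that scale, 56.1% to 64.6% of low-ranked ones and 88.4% to 97.1% of high-ranked ones were recovered. The scale was set from the median fold enrichment of the lists and the fold of their last peak by -log10 p. That peak need not have a low fold: in AF9-experienced PBS 4 it had 22.6 against a median of 18.6. The simulated folds therefore do not measure how well real 2-fold or 4-fold changes are found. All simulated libraries had the same independent noise, with no weakly enriched library and no batch. False calls in the real data can therefore be more numerous. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and data.table (version 1.17.8).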

Results

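HSPCs came from mice carrying a mixed transplant. In AF9-experienced mice, 200000 marrow cells with a doxycycline-inducible MLL-AF9 fusion, a leukaemia driver, were given with 800000 wild-type marrow cells. Naive control mice received marrow with the inducer alone in place of the MLL-AF9 marrow. After 6 to 8 weeks, doxycycline was given for 5 weeks and withdrawn for 4 weeks, which models leukaemia and then remission. Mice were injected with PBS or with LPS, a bacterial lipopolysaccharide that activates Toll-like receptor 4, and the wild-type donor HSPCs were sorted 24 hours later. There were 4 naive PBS, 3 naive LPS, 4 AF9-experienced PBS and 5 AF9-experienced LPS replicates. The comparisons ask what LPS does to open chromatin in wild-type HSPCs, whether past exposure to MLL-AF9 cells leaves a mark on it, and whether that exposure alters the LPS response.

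The lists held 19448 peaks (naive PBS 1) to 88816 peaks (AF9-experienced PBS 3). Means were 60272 ± 28249 peaks in naive PBS (SD, n = 4), 60421 ± 19165 in naive LPS (n = 3), 71809 ± 30820 in AF9-experienced PBS (n = 4) and 69055 ± 10474 in AF9-experienced LPS (n = 5). None of the 4 comparisons of peak number passed an exact permutation test (p = 0.457 to 0.971; adjusted p = 0.929 to 0.971; the smallest p possible is 0.0159 to 0.0571). The 3 shortest lists were naive PBS 1 (19448), AF9-experienced PBS 1 (25685) and naive LPS 3 (39464). The median fold enrichment of the equal-length lists, the authors' value, was 13.9 to 19.4 in the other 6 PBS libraries and 9.16 to 13.6 in the other 7 LPS libraries, against 5.07, 5.34 and 6.58 in the short lists. Over all libraries this measure differed by -3.60 after LPS in naive mice (exact p = 0.4) and by -4.63 in AF9-experienced mice (exact p = 0.175). Gene-end regions made up 48.9% ± 0.786 of the equal-length lists in naive PBS (n = 4), 48.4% ± 2.05 in naive LPS (n = 3), 48.2% ± 0.544 in AF9-experienced PBS (n = 4) and 47.1% ± 1.3 in AF9-experienced LPS (n = 5). Exact permutation p for this share was 0.159 to 0.743 over the 4 comparisons (adjusted p = 0.4 to 0.743).

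**Figure D1:**
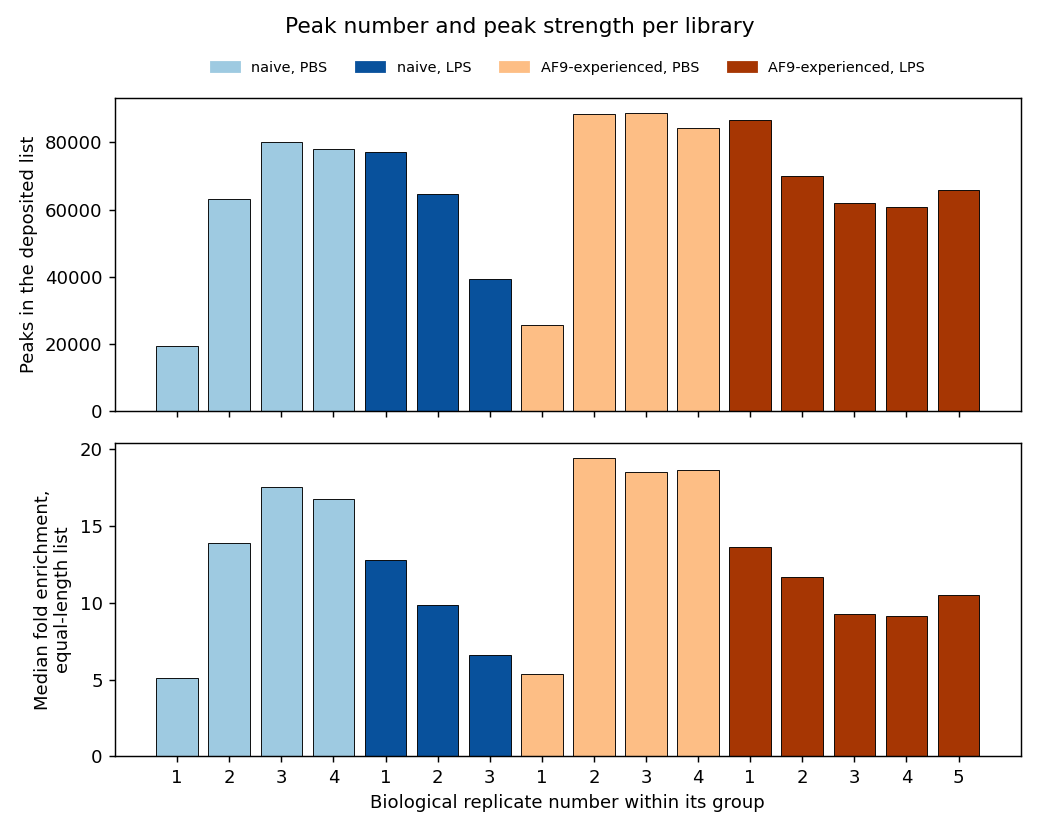
Number of peaks per library and median fold enrichment of its 19100 strongest autosomal peaks, by group (n = 4, 3, 4 and 5 libraries). Naive PBS 1, AF9-experienced PBS 1 and naive LPS 3 have the fewest peaks, 19448, 25685 and 39464.

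Libraries differed most between LPS and PBS, groups that outside the short lists also differ in median fold enrichment. The first principal component of the region values held 25.8% of the variance and placed the 8 LPS libraries at 495 to 1131 and the 8 PBS libraries at -1198 to -300. The second held 16.2% and set naive PBS 1 (1981) and AF9-experienced PBS 1 (1302) apart. In AF9-experienced mice, lists shared more regions within a treatment (mean Jaccard index 0.772) than between treatments (0.713), a difference of 0.0591 (exact p = 0.00794, the smallest possible, adjusted p = 0.0317). With full lists in place of equal-length lists, this difference no longer passed. In naive mice the difference was 0.0451 (0.730 against 0.685; exact p = 0.0571; adjusted p = 0.114). Between AF9-experienced and naive libraries it was -0.00835 after PBS (0.747 against 0.755; exact p = 0.686) and 0.00466 after LPS (0.766 against 0.762; exact p = 0.357), neither past the test.

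**Figure D2:**
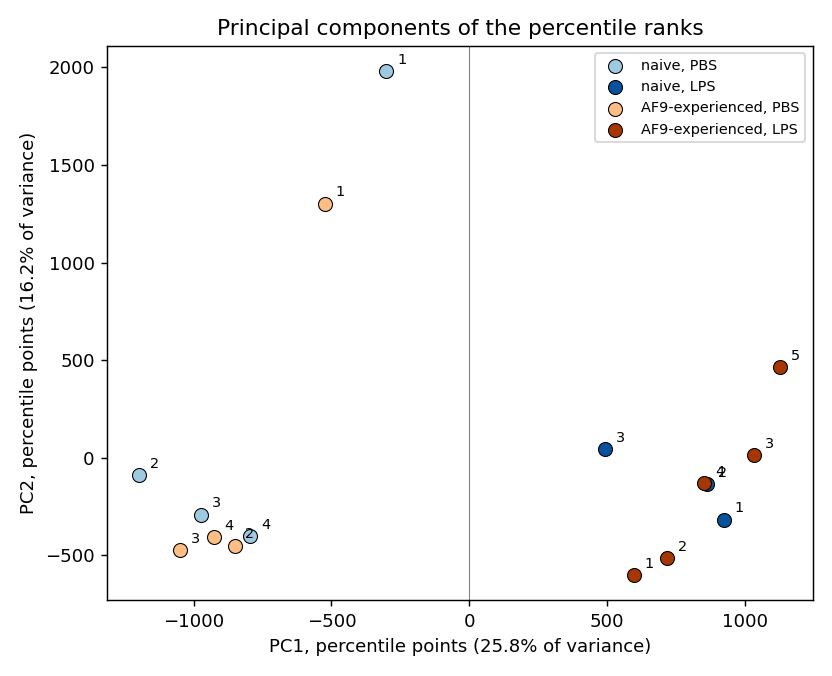
Scores of the 16 libraries on the first (25.8% of variance) and second (16.2%) principal components of the percentile ranks, coloured by group. The 8 LPS libraries lie at 495 to 1131 on the first component and the 8 PBS libraries at -1198 to -300; the short lists naive PBS 1 and AF9-experienced PBS 1 lie highest on the second.

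In naive mice, the region at the gene end of Cxcl10, an interferon-induced chemokine (chromosome 5, 92348343 to 92349140), rose by 49.6 percentile points after LPS (SE 8.33; adjusted p = 0.00182), from 0.945 ± 1.89 (SD, n = 4) to 50.6 ± 12.7 (n = 3). The smallest adjusted p for a rise included a region inside Slc17a4, an organic anion transporter gene (chromosome 13, 23913762 to 23914378), which stood at 65.9 ± 7.57 after LPS (3 of 3 lists) against 3.47 ± 6.93 after PBS (1 of 4 lists; adjusted p = 4.7e-04). The smallest adjusted p for a fall included a region 20.7 kb from Tcf7l1, a transcription factor of the Wnt pathway (chromosome 6, 72809709 to 72810749), which stood at 6.43 ± 5.88 after LPS (n = 3) against 75.7 ± 3.86 after PBS (n = 4), a difference of -69.2 (SE 8.80; adjusted p = 4.7e-04). A region inside Clcf1, an IL-6 family cytokine gene, was in all 4 PBS lists (50.8 ± 11.5) and in none of the 3 LPS lists. Beside Slc17a4, regions inside the DNA repair gene Xrcc4 (+59.9), Glis1 (+54.0), Ccdc97 (+55.8) and Pkd1l2 (+56.8) and 19.7 kb from Sema4b (+57.6) rose. Regions 40.9 kb from the growth factor gene Pdgfa (-58.1) and inside Abca4 (-60.0), Magi1 (-51.7) and Stk10 (-43.2) fell.

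Of the 23554 regions tested in naive mice, 471 were called higher and 287 lower after LPS, with median differences of 36.5 and -35.5 percentile points (median SE 8.08 and 8.17). They were linked to 404 and 254 genes. Gene ends made up 13.6% of those called higher and 13.9% of those called lower, against 42.5% of all tested regions. By list, 5 of 17 measured MLL-AF9 program members rose, among them Pbx3 (+45.4), Eya1 (+39.4) and the cell cycle kinase gene Cdk6 (+36.9), and Id2 fell (-28.6). In the lymphoid priming list, Tcf7 (-44.1), Bcl11a (-36.7) and the gene end of the receptor tyrosine kinase gene Flt3 fell, Igll1 rose (+34.5), and 12 of 16 measured members did not pass. The Flt3 end went from 90.7 ± 3.32 (n = 4) to 79.4 ± 4.68 (n = 3; adjusted p = 0.0174), but ranked by fold enrichment it differed by +16.1. Of 31 measured NF-kB and TLR members, Birc3 (+16.5) and Nfkb1 (+38.1) rose. Csf1r, the receptor of a macrophage growth factor (-34.8), fell; it stands in both the granulocyte-monocyte progenitor list, where Klf4 rose (+35.2), and the monocyte-macrophage list, where Cx3cr1 rose (+26.8). One member moved in each of several lists: Erg rose in HSC identity (+38.4), Zfpm1 in megakaryocyte-erythroid (+39.7), Cd200r3 in mast cell and basophil (+44.5), Cxcl10 in interferon-stimulated (1 of 32), and Klf4 in AP-1. In the same way Ltf fell in neutrophil granule (-23.0) and Ywhaz in housekeeping control (-24.2). Cish rose (+27.9) and a region 5.7 kb from Socs3 fell (-29.3) in the IL6-STAT3 list, and Cdk6 and Mki67 (+40.2) rose in cell cycle. No member of the mature lymphocyte, endothelial and stromal or antigen presentation lists was called. Leaving out 1 library ended 15 of these calls, given here with the library that raised the adjusted p most: without naive LPS 2, those at Cish (adjusted p = 0.192), Id2 (0.140), Socs3 (0.127), Cd200r3 (0.107), Nfkb1 (0.0792), Mki67 (0.0782) and Cdk6 (0.0611); without naive LPS 1, Zfpm1 (0.172), Klf4 (0.131) and Birc3 (0.0933). Without naive LPS 3 those at Igll1 (adjusted p = 0.101), Flt3 (0.0856), Ltf (0.0810) and Ywhaz (0.0550) ended, and without naive PBS 3 that at Cx3cr1 (0.0522). Most of these calls hung on more than 1 library. The number of libraries whose loss alone ended the call was 9 at Cish, 7 at Socs3 and Zfpm1, and 5 at Cd200r3. It was 4 at Nfkb1, Flt3 and Igll1 and 1 to 3 at the others. The 12 regions with the smallest p in naive mice and those near Cxcl10, Tcf7, Bcl11a, Csf1r, Pbx3, Eya1 and Erg were called without any 1 library.

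Adjusted over the list alone, calls matched these except for Itgam (granulocyte-monocyte progenitor), Cd177 and Fpr2 (neutrophil granule), Gata2 (mast cell and basophil), Tie1 and Kdr (endothelial) and Ifitm3 (interferon), which were added. No list passed camera in naive mice. The smallest adjusted p was 0.0540, for lower neutrophil granule regions (mean difference -11.7; 6 members measured; adjusted p = 0.171 with an estimated correlation), and 0.143 for higher NF-kB and mast cell regions. Fry's adjusted p was 0.00680 for the neutrophil list, 0.0132 for MLL-AF9, 0.0156 for NF-kB and for cell cycle, and 0.0246 for mast cell. The share of NF-kB regions holding a peak was 79.9% ± 0.849 after LPS (n = 3) and 68.8% ± 3.26 after PBS (n = 4; exact p = 0.0571, the smallest possible; adjusted p = 0.486). Among gene ends always examined, Irf8, Irf1, Cebpb, Nfkbia, Socs3, Meis1, Hoxa9 and Mecom were not called; the Socs3 end differed by +11.8 (adjusted p = 0.156). All 3 naive LPS libraries had 2 peaks on chromosome Y and the naive PBS libraries 0 or 1, so a value within libraries of 1 kind cannot be had; with Y peaks as covariate, 136 regions were called higher and 15 lower. As presence in full lists, Xrcc4 and Erg differed by -0.0327, and Clcf1 by 0.25 at a -log10 q of at least 5. Counts also hung on how peaks were ranked: 2 higher and 2 lower by fold enrichment, 25 and 27 with 9550 peaks per list, 129 and 3 with 50% overlap, 3 and 0 as presence at a -log10 q of at least 5, none as presence in full lists, 869 and 663 without the 3 short lists (2734 and 1981 with 59609 peaks per list), 1731 and 1491 with library weights, and 163 and 85 in a fit of both groups alone. Called higher regions numbered 268 without naive PBS 2, 259 without naive PBS 3, 287 without naive LPS 1 and 234 without naive LPS 2. Called lower regions numbered 572 without naive PBS 1, 167 without naive PBS 2, 124 without naive PBS 3, 182 without naive LPS 1, 109 without naive LPS 2 and 141 without naive LPS 3.

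In AF9-experienced mice, a region inside Il1b, which encodes the cytokine interleukin 1 beta (chromosome 2, 129367991 to 129368507), was in all 5 LPS lists (39.6 ± 13.4) and in none of the 4 PBS lists (difference 39.6, SE 7.15, adjusted p = 0.00206). The Birc3 gene end rose from 72.6 ± 6.23 (n = 4) to 90.3 ± 1.76 (n = 5), and a region inside Nfkb2, an NF-kB subunit gene, from 79.5 ± 2.05 (n = 4) to 92.8 ± 3.85 (n = 5). A region inside Il6ra, an IL-6 receptor gene, was in all 4 PBS lists (37.0 ± 16.1) and in none of the 5 LPS lists (difference -37.0, SE 7.44, adjusted p = 0.00474). The smallest adjusted p was shared by Slc17a4, Xrcc4 and Sema4b for a rise, with Slc17a4 at 67.0 ± 4.25 after LPS (5 of 5 lists) and 4.08 ± 5.38 after PBS (2 of 4 lists; adjusted p = 3.2e-05). For a fall it was that of the region near Pdgfa, at 4.65 ± 9.58 (n = 5) against 55.8 ± 3.17 (n = 4; adjusted p = 1.2e-04). Regions inside Xrcc4 (+63.6), Ltbp1 (+58.5), Clic4 (+56.5) and Tmbim1 (+28.4) and near Sema4b (+64.0) also rose. Falls included the gene end of Sla2, an adaptor of lymphocyte receptors (-53.3), and regions 5.0 kb from Zyx (-49.1), inside Endou (-48.7), 39.2 kb from Rplp1 (-52.1) and 35.1 kb from Ptprf (-46.8).

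In AF9-experienced mice 810 regions were called higher and 411 lower after LPS, with median differences of 32.3 and -29.0 (median SE 7.28 and 7.27), linked to 676 and 362 genes. Gene ends made up 11.9% and 19.5% of them. Of the 31 measured NF-kB and TLR members, 6 rose, among them Il1b, Birc3, Nfkb2 and Nos2 (+18.9), and none fell; adjusted over the list alone the count was 7, with Tnfaip3. This list alone passed camera (mean difference 4.64; adjusted p = 0.0290; adjusted p = 0.168 with an estimated correlation). In naive mice its mean difference was nearly as large, 4.41 (camera adjusted p = 0.143). The LPS change of the list differed between backgrounds by 0.221 (interaction, camera adjusted p = 0.774). The call in AF9-experienced mice was lost without AF9-experienced PBS 3 (adjusted p = 0.0729), AF9-experienced PBS 4 (0.113) or AF9-experienced LPS 5 (0.0869). It was also lost by fold enrichment (adjusted p = 0.231), without the 3 short lists at 59609 peaks per list (0.0622; mean difference 2.26), where AP-1 passed in its place, and there with library weights (0.0642), with fixed-width windows (0.0614), 50% overlap (0.173), the replicate number as a block (0.127), median fold as covariate (0.143) and only the AF9-experienced LPS libraries with Y peaks (0.488). The share of its regions holding a peak was 81.5% ± 5.66 after LPS (n = 5) and 66.5% ± 5.55 after PBS (n = 4; exact p = 0.0159, the smallest possible; adjusted p = 0.0899). As presence in full lists its mean difference was -0.0595 (adjusted p = 0.881), and -0.0678 at a -log10 q of at least 5 (adjusted p = 0.543).

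Among AP-1 and immediate early genes, 4 of 22 rose, Klf4 (+54.5), the stress-induced factor Atf3 (+24.2), Junb (+16.7) and Fosb (+17.3), and Nr4a1 (-34.3) and Btg2 (-33.5) fell; adjusted over the list alone 6 rose, with Ier2 and Zfp36. In the MLL-AF9 program Cdk6 (+45.3), the survival gene Bcl2 (+45.3) and Pbx3 (+30.7) rose and a region inside Mecom, a stem cell factor gene, fell (-27.4), with 13 of 17 not called; adjusted over the list alone 6 rose and 3 fell. In HSC identity Erg (+33.7) rose and Prdm16 (-40.9) and Mecom fell, with Runx1 added over the list alone. Lymphoid priming regions near Bcl11a (-27.5), at Notch1 (-18.0) and inside Lef1 (-27.6) fell and none of 16 rose; Ccr9 was added over the list alone. The share of that list's regions holding a peak was 67.9% ± 3.03 after LPS (n = 5) and 81.4% ± 3.29 after PBS (n = 4; exact p = 0.0159; adjusted p = 0.0899). Klf4 and Csf1r (-27.2) moved in the granulocyte-monocyte progenitor list, and of 10 monocyte-macrophage members only Csf1r was called. Interferon-stimulated members Cxcl10 (+35.6) and Nmi (+36.0) rose and 30 of 32 were not called. Zfpm1 (+40.6) and Pf4 (+23.4) rose in megakaryocyte-erythroid, Cd200r3 (+47.9) in mast cell and basophil, Emcn (+27.4) in endothelial and stromal, and Tap2 (+17.2) in antigen presentation. Cish rose (+29.3) and Il6ra fell in the IL6-STAT3 list, and Cdk6 and Mki67 (+28.5) rose in cell cycle. No neutrophil granule, mature lymphocyte or housekeeping member was called. Adjusted over the list alone, Nfe2, Socs3, Il4ra, Mcm5 and Cdk1 were added in these lists and Tap2 was lost. Of the calls named for these lists over all tested regions, leaving out 1 library ended 15, given with the library that raised the adjusted p most: without AF9-experienced PBS 4, those at Lef1 (adjusted p = 0.166), Mecom (0.132), Pf4 (0.132), Bcl11a (0.0985) and Prdm16 (0.0509); without AF9-experienced PBS 3, Emcn (0.123), Mki67 (0.117), Nr4a1 (0.103), Nos2 (0.0625) and Cish (0.0573). Without AF9-experienced PBS 1 those at Tap2 (adjusted p = 0.108) and Notch1 (0.106) ended, without AF9-experienced PBS 2 those at Fosb (0.123) and Junb (0.0990), and without AF9-experienced LPS 2 that at Btg2 (0.0990). The number of libraries whose loss alone ended the call was 13 at Lef1, 12 at Emcn and Fosb, 10 at Btg2 and 9 at Mecom and Notch1. It was 7 at Junb, Mki67, Nr4a1 and Tap2, 6 at Pf4 and 1 to 3 at the others. The 12 regions with the smallest p and those near Il1b, Birc3, Nfkb2, Klf4, Atf3, Cdk6, Bcl2, Pbx3, Erg, Il6ra and Cxcl10 were called without any 1 library. Fry's adjusted p was 0.00670 for NF-kB, 0.00831 for cell cycle and 0.0112 for MLL-AF9.

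The gene ends always examined were not called in AF9-experienced mice; the nearest was Socs3 (68.3 ± 3.71 to 81.0 ± 3.43, adjusted p = 0.0518), and Flt3 differed by -3.51 (adjusted p = 0.433). AF9-experienced LPS 1 and 2 had 3 and 2 Y chromosome peaks and the other AF9-experienced libraries none. Without the 5 libraries with 2 or more Y peaks, which include all naive LPS libraries, 902 regions were called higher and 246 lower. With AF9-experienced LPS 1 and 2 as the only AF9-experienced LPS libraries, 462 and 197 were. Counts were 242 higher and 139 lower by fold enrichment, 137 and 58 with 9550 peaks per list, 273 and 32 with 50% overlap, 4 and 0 as presence at a -log10 q of at least 5, none as presence in full lists, 1332 and 1140 without the 3 short lists (3453 and 3872 with 59609 peaks per list), and 2092 and 2007 with library weights. Full lists held peaks for many called regions in both treatments: as presence there, Slc17a4, Pbx3, Nmi, Cdk6, Mki67 and Nos2 differed by -0.0230 and Mecom by 0.206. Mecom and Lef1 differed by 0.25 at a -log10 q of at least 5, while Notch1 differed by +11.6 when ranked by fold enrichment. Called higher regions numbered 488 without AF9-experienced PBS 2, 435 without AF9-experienced PBS 3 and 460 without AF9-experienced PBS 4. Called lower regions numbered 640 without naive PBS 1, 234, 193 and 162 without AF9-experienced PBS 2, 3 and 4, and 245, 251 and 255 without AF9-experienced LPS 2, 3 and 4.

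The LPS changes in both backgrounds pointed the same way. Slc17a4, Xrcc4, Sema4b, Cxcl10, Birc3, Klf4, Cdk6, Pbx3, Erg and Cd200r3 rose in both, and regions near Pdgfa and Bcl11a and inside Csf1r fell in both. The Il1b region, called in AF9-experienced mice alone, was also in every naive LPS list and in no naive PBS list. The Il6ra region, likewise called there alone, was also in every naive PBS list and in no naive LPS list. In all, 300 regions were called higher in both (16.2 expected if calls were independent) and 127 lower in both (5.01 expected). None was called in opposite directions. Both contrasts share 1 estimate of each region's spread, so calls are not independent and the expected counts can be too low. Of the 758 regions called in naive mice, 97.8% had the same sign in AF9-experienced mice, where their median differences were 30.9 and -22.9. Of the 1221 called in AF9-experienced mice, 97.6% had the same sign in naive mice, with medians of 24.7 and -23.0. Across all 23554 tested regions the 2 LPS effects, which share no library, correlated at r = 0.690 (jackknife SE over libraries 0.106); regions are not independent replicates.

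**Figure D3:**
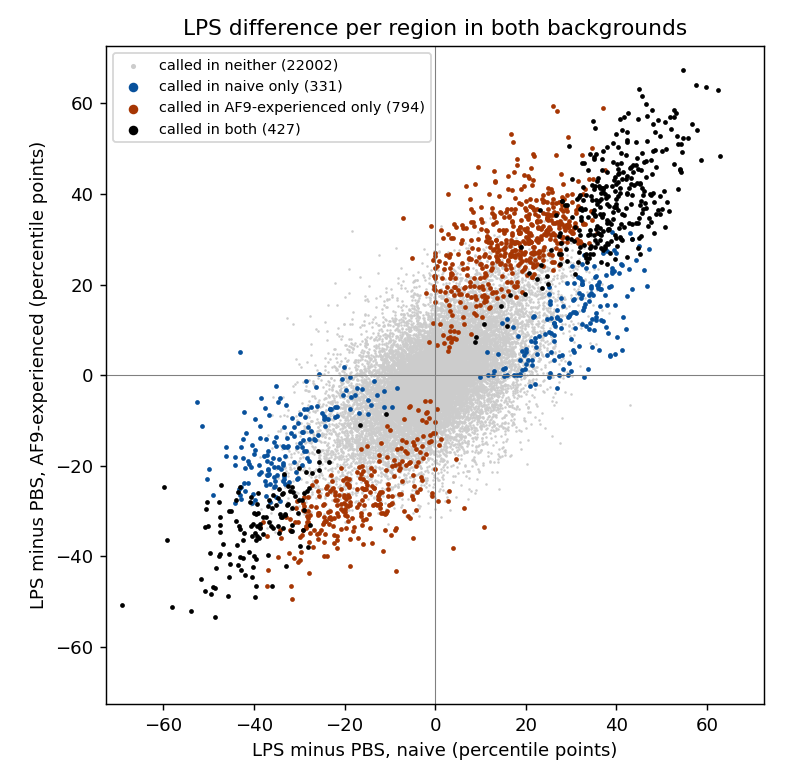
Change after LPS in naive (x) and in AF9-experienced mice (y), in percentile points, for the 23554 tested regions, coloured by where each was called: 331 in naive mice alone, 794 in AF9-experienced mice alone, 427 in both and 22002 in neither. Regions called in both lie in the lower left and upper right quadrants.

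After PBS, no region was called different between AF9-experienced and naive mice. Nfic, a nuclear factor I gene, held the smallest p among higher regions (chromosome 10, 81413663 to 81414513; 35.6 ± 7.34 in AF9-experienced PBS against 2.90 ± 3.92 in naive PBS, n = 4 each; difference 32.7, SE 6.79, adjusted p = 1). Next came regions 13.0 kb from Vegfa (+22.4) and inside Maml3 (+20.4), and on the lower side inside Atp2b1 (-19.7), at the end of Tdrd3 (-10.6) and inside Arntl (-27.4), all at adjusted p = 1. Gene ends of the leukaemia program factors Meis1 (51.6 ± 6.69 against 40.7 ± 7.96) and Hoxa9 (41.4 ± 12.8 against 51.6 ± 5.87, n = 4 each) did not pass either (adjusted p = 1). Limma called 0 regions in either direction; at an unadjusted p under 0.05 there were 423 higher and 331 lower, 3.20% of those tested. No member of any list was called, nor was any adjusted over the list alone, and no list passed camera (smallest adjusted p = 0.671). Fry's adjusted p was at least 0.932. Library weights called 13 regions higher and 15 lower (92 and 47 without the short lists and with 59609 peaks per list), and presence in the equal-length lists 57 and 28. Without AF9-experienced PBS 1, the AP-1 list passed as lower (adjusted p = 0.0305).

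After LPS, 3 regions were lower in AF9-experienced than in naive mice, and none was higher. They lie inside Rnf180, a ubiquitin ligase gene (chromosome 13, 105139872 to 105140333), Fyb, a T cell adaptor gene (chromosome 15, 6574437 to 6574978), and Akap13, an A-kinase anchoring protein gene (chromosome 7, 75699641 to 75700258). Rnf180 stood at 0.977 ± 2.18 in AF9-experienced LPS (n = 5) and 30.0 ± 5.36 in naive LPS (n = 3; difference -29.1, SE 4.18, adjusted p = 0.01). Fyb stood at 1.42 ± 1.99 against 28.3 ± 2.20 (difference -26.9, SE 3.98, adjusted p = 0.01) and Akap13 at 0 against 29.3 ± 12.9 (difference -29.3, SE 4.78, adjusted p = 0.0269). Each was in all 3 naive LPS lists, in 1, 2 and 0 of the 5 AF9-experienced LPS lists and in no PBS list, while the full lists held all 3 regions in all 5 AF9-experienced LPS and all 3 naive LPS libraries, and each region in 3 of 4 naive PBS and 3 or 4 of 4 AF9-experienced PBS libraries. Regions inside Sdccag8 (+37.0, adjusted p = 0.144), near Adamtsl4 (+25.8, adjusted p = 0.285) and inside Dym (+37.1, adjusted p = 0.285) were higher without passing. Limma called 0 regions higher; at an unadjusted p under 0.05 there were 677 higher and 592 lower. Leaving out AF9-experienced LPS 4 raised the adjusted p to 0.0519 for Rnf180 and Fyb and 0.106 for Akap13. The number of libraries whose loss alone ended the call was 10 at Akap13 and 2 each at Rnf180 and Fyb. The lower count was 0 without AF9-experienced LPS 3 or 4, 9 without naive LPS 1 or AF9-experienced LPS 5, and 0 with Y peaks as covariate, by fold enrichment, with 9550 peaks per list or in a fit of both groups alone; the higher count was 1 without naive LPS 1 or AF9-experienced LPS 1, 3 without AF9-experienced LPS 5, and 30 as presence in the equal-length lists, where 13 were lower. No list member was called, also adjusted over the list alone, and no list passed camera (smallest adjusted p = 0.444, neutrophil granule).

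The LPS change itself was not called different between backgrounds at any region. Rnf180 (-29.1), Fyb (-26.9) and Akap13 (-29.3) had the smallest p for a smaller rise in AF9-experienced mice (adjusted p = 0.880, 0.880 and 1), and regions 9.4 kb from Dhrs7 (+46.7), inside Sdccag8 (+37.0) and inside Pla1a (+37.2) for a larger one (adjusted p = 1 each). Limma's interaction test called 0 regions; at an unadjusted p under 0.05 there were 316 higher and 377 lower, 2.94% of those tested. Presence in the equal-length lists called 2 in each direction. One list, neutrophil granule and mature granulocyte, passed camera: its 8 regions, linked to 6 measured members, had an LPS change 10.1 points higher in AF9-experienced than in naive mice (adjusted p = 0.0425; adjusted p = 0.148 with an estimated correlation). None of these members was called for the difference, and the next list was AP-1 (adjusted p = 0.503). The neutrophil call was kept when naive PBS 2, naive PBS 4, AF9-experienced PBS 2, AF9-experienced PBS 3 or AF9-experienced LPS 1 was left out and lost without any 1 of the other 11 libraries. Without these the adjusted p was 0.104 (naive PBS 1), 0.184 (naive PBS 3), 0.0778, 0.0919 and 0.0837 (naive LPS 1, 2 and 3), 0.104 and 0.234 (AF9-experienced PBS 1 and 4), and 0.0844, 0.0667, 0.0509 and 0.0683 (AF9-experienced LPS 2, 3, 4 and 5). The difference was +17.7 with 9550 peaks per list, +7.08 without the 3 short lists at 19100 peaks and -4.54 without them at 59609 peaks. Without them, or with 9550 peaks, the call was lost. It was also lost by fold enrichment (+7.82, adjusted p = 0.359), with 50% overlap (+1.74, 0.739), library weights (+7.67, 0.213) and Y peaks as covariate (+9.32, 0.195). Fixed-width windows (adjusted p = 0.0656), list length (0.0681) or median fold (0.0716) as covariate and the replicate block (0.0674) ended it too. Without AF9-experienced PBS 1, AP-1 passed as higher instead (adjusted p = 0.0279).

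**Figure D4:**
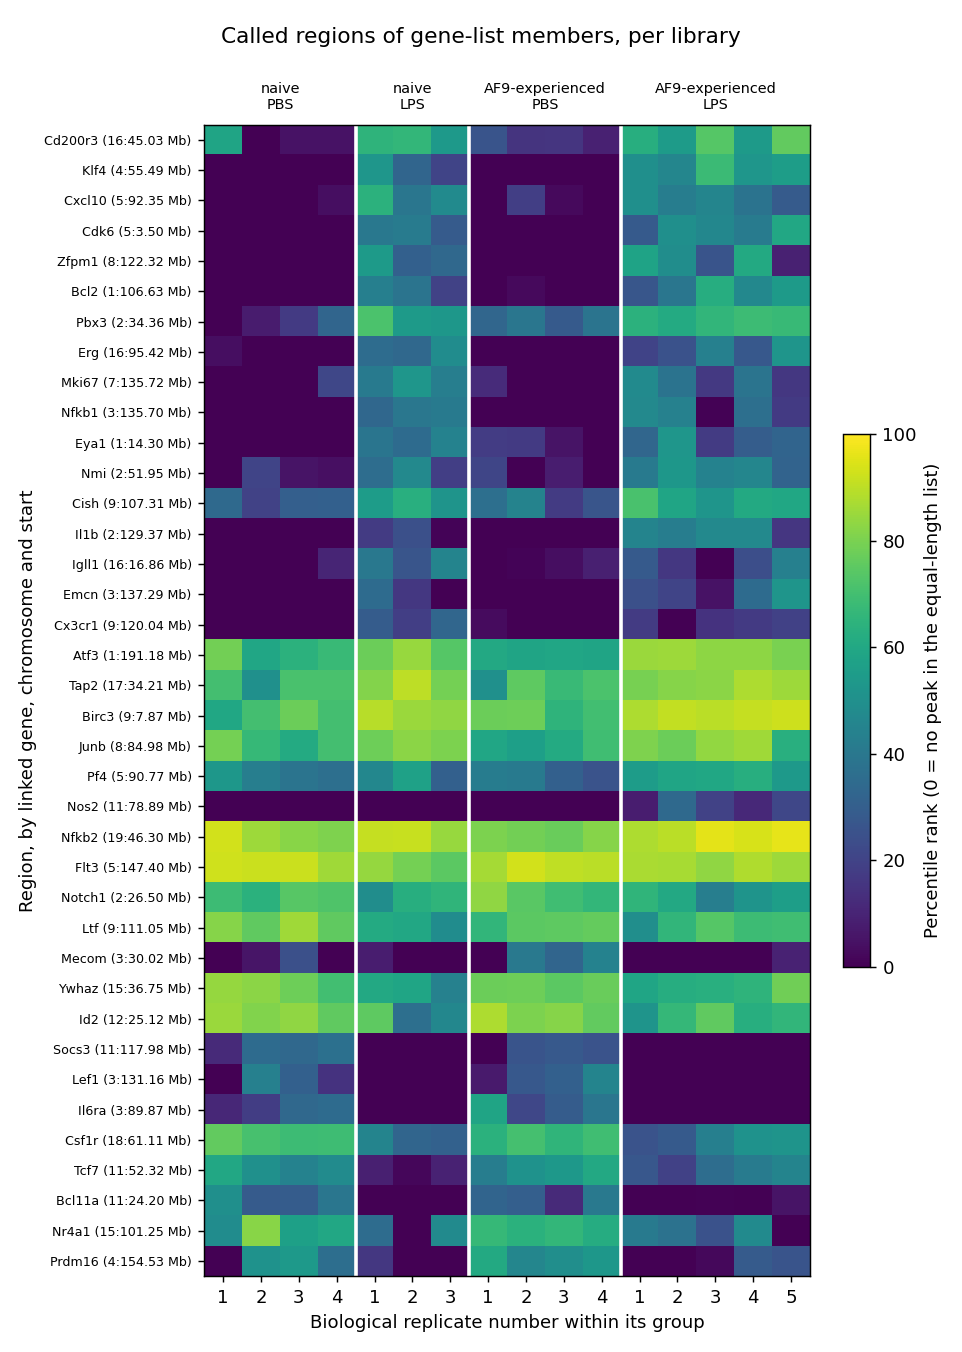
Percentile rank of 38 regions linked to members of the gene lists (lines) in the 16 libraries (columns, by group); 0 means no peak among the 19100 strongest. The upper 24 regions were called higher after LPS in at least 1 background and the lower 14 lower.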

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

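Chosen only after the result was seen were the tests on Y chromosome peaks in AF9-experienced mice and on the Sca-1 gate, and the covariates for median fold enrichment and Y peaks. Of 255 groups of 4 or 5 libraries examined, 42 had 1 library far from the others (12.75 expected, since chance flags about 1 in 20 groups). The library was naive PBS 4 in 10 of them, AF9-experienced PBS 1 in 8, naive PBS 1 and AF9-experienced LPS 5 in 7 each, AF9-experienced PBS 2 in 5, AF9-experienced LPS 3 in 3, and naive PBS 2 and AF9-experienced LPS 2 in 1 each.

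AF9-experienced PBS 1 stood apart in peak number (25685) and median fold enrichment (5.34). Its percentile ranks were apart at Cebpb (0), Magi1 (52.8), Mki67 (12.3), Ltf (65.7), Cx3cr1 (2.92) and the region 5.7 kb from Socs3 (0). Naive PBS 1, also a short list, was apart at Cebpb (0), Zyx (22.1), the same Socs3 region (11.8), Xrcc4 (19.7), Cd200r3 (58.6), Erg (3.66) and Clcf1 (33.7). Naive PBS 4 was apart at Adamtsl4 (11.6), Clic4 (13.5), Cxcl10 (3.78), Flt3 (85.7), Ccdc97 (2.89), Sema4b (18.0), Mki67 (21.4), Pkd1l2 (5.76), Slc17a4 (13.9) and Igll1 (10.5). In these regions except Flt3 the other 3 naive PBS libraries had no peak among the strongest, and the test then picks out any library with one. AF9-experienced PBS 2 was apart at Bcl2 (2.47), Cxcl10 (18.7), Sema4b (15.8), the Socs3 gene end (73.8) and Dym (31.4), and naive PBS 2 at Tap2 (50.3). AF9-experienced LPS 5 was apart at Il1b (15.9), the region inside Mecom (9.69), the Mecom gene end (61.5), Pdgfa (21.8), Rplp1 (3.85), Bcl11a (5.19) and Rnf180 (4.88). AF9-experienced LPS 3 was apart at Sema4b (80.1), Endou (4.76) and Vegfa (2.96), and AF9-experienced LPS 2 at Cx3cr1 (0).

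Peaks on chromosome Y, which no comparison used, appeared in naive LPS 1, 2 and 3 (2 each), AF9-experienced LPS 1 (3) and AF9-experienced LPS 2 (2). They lay at the ends of Eif2s3y, Uty and Kdm5d. No PBS library had more than 1 (naive PBS 3). Peaks at the end of Xist numbered 0 in naive LPS 1, naive LPS 3 and naive PBS 1 and 1 or 2 in the other libraries.

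The regions called by LPS could come from a technical difference between LPS and PBS libraries. Lower enrichment of the LPS libraries was tested with AF9-experienced PBS 1 and naive PBS 1, which are weakly enriched (median fold 5.34 and 5.07). They shifted the regions called in the other background by a median of 0 times the LPS difference. Mean shifts were 2.97 against 35.8 and 5.53 against 31.5, and 41.8% and 45.9% of the regions shifted the way of LPS. With median fold as covariate 756 of 758 and 1192 of 1221 calls were kept. Both libraries also set the spread used for the calls, so regions they shift strongly were less likely to be called. The shift was thus small at the called regions, but lower enrichment as a cause is not excluded. The batch or sex marked by Y peaks as the whole cause is argued against in AF9-experienced mice, where 60.8% of calls (742 of 1221) were kept in a fit without the 5 libraries with 2 or more Y peaks, all naive LPS libraries among them. It is also argued against for 698 of the 758 regions called in naive mice, which could be matched in the AF9-experienced libraries without Y peaks. Their median difference there was 27.7, which is 0.764 times the naive median of 36.2, and 680 (97.4%) had the same direction. The other called regions had a peak in too few lists to be tested without the libraries with Y peaks. Regions with peaks mainly in libraries with Y peaks would be among them, so the batch or sex is not argued against there. In naive mice Y peaks go with LPS, so their share of the size is open: with Y peaks as covariate 90 of 758 calls were kept, with a median difference of 32.8 against 36.2 before and a median SE of 12.1 against 8.13, the wider error being why calls ended. Sca-1 is itself raised by inflammation, so the gate may take in myeloid progenitors, which cannot be told apart from a change within cells. The granulocyte-monocyte progenitor list was higher in naive and AF9-experienced mice (12 members measured, mean differences 3.70 and 5.14) without passing camera (adjusted p = 0.313 and 0.301). In it Klf4 rose and Csf1r fell. The share of its regions holding a peak went from 61.5% to 75.6% in naive and from 64.4% to 76.2% in AF9-experienced mice (exact p = 0.114 and 0.0952). The HSC identity list did not pass as lower. A response of the cells to LPS stays open as well.

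The neutrophil granule and mature granulocyte list differed between backgrounds in its LPS change by the interaction test (adjusted p = 0.0425; mean difference 10.1; 8 regions). Chance cannot be excluded: in 9 of 100 regroupings within PBS and within LPS, the real one included, some gene list had a camera p as small (0.00250; the lowest of the others 3.3e-04). For this list alone 1 regrouping, the real one, did (lowest of the others 0.0237), but it was picked as the list that passed, so that count does not decide. The call ended with an estimated correlation (adjusted p = 0.148), and the difference was 17.7 with 9550 peaks per list, 7.08 without the 3 short lists at 19100 peaks and -4.54 without them at 59609 peaks, none of them called. The mean LPS difference of the list was -11.7 in naive and -1.51 in AF9-experienced mice. With Y peaks as covariate the difference was 9.32 (camera adjusted p = 0.195), and with median fold enrichment as covariate 10.2 (0.0716), so it stayed about as large while the call ended. No other technical explanation and no biological one was tested.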

How the results depend on the processing

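The tests chosen only after the data were seen are the median fold and Y peak covariates, the settings by Y peaks, the short lists left out at 19100 peaks or with library weights, and full lists for regions seen in 1 treatment alone. Counts are given as regions higher and lower. Here naive means LPS minus PBS in naive mice (main counts 471 and 287), AF9 means LPS minus PBS in AF9-experienced mice (810 and 411), and lists means gene lists passing camera (main counts 1 higher in AF9 and 1 higher in the interaction, else 0). Calls changed more often than directions: of the values of called named regions, 1048 of 1561 kept direction and call under alternatives, 499 lost the call and 14 reversed; leaving out 1 library, 1092 of 1245 kept it, 153 lost it and none reversed. The cause of each change was not tested unless given. The correlation of both LPS effects stayed between 0.504 and 0.819 under the alternatives and when 1 library was left out. Motif tests and their window alternative were not run. Read depth is unknown; list length limits which weak peaks are seen.

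Ranking by fold enrichment gave 2 and 2 regions in naive, 242 and 139 in AF9 and 0 lower in AF9-experienced than naive after LPS; lists were 1 higher after LPS between backgrounds, 0 in AF9 and 0 in the interaction, and r was 0.819. At the regions called in naive the median difference was 35.5 against 36.2 and the median SE 12.7 against 8.13, so the wider error ended the calls. Flt3 in naive reversed to 16.1 and Notch1 in AF9 to 11.6. Lists of 9550 peaks gave 25 and 27 in naive, 137 and 58 in AF9 and 0 lower after LPS between backgrounds, with 1 list lower in naive, 2 higher in AF9 and 0 in the interaction; fewer regions could hold a peak.

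Without the 3 short lists, at 59609 peaks, counts were 2734 and 1981 in naive, 3453 and 3872 in AF9, and 1 and 8 between backgrounds after LPS; lists were 0 in the interaction, where the neutrophil difference reversed to -4.54, and in AF9 the 1 list was AP-1 (2.96, adjusted p = 0.0256) in place of NF-kB (2.26, adjusted p = 0.0622). At 19100 peaks they were 869 and 663 in naive and 1332 and 1140 in AF9, with 1 list higher in naive, 2 in AF9 and 0 in the interaction (neutrophil difference 7.08). Adding library weights at 59609 peaks gave 3959 and 3555 in naive, 5394 and 7471 in AF9, 92 and 47 between backgrounds after PBS, 0 lower after LPS and 1 lower in the interaction, with lists 2 higher in naive, 0 in AF9 and 0 in the interaction (neutrophil difference reversed to -4.10). Library weights alone gave 1731 and 1491 in naive, 2092 and 2007 in AF9, 13 and 15 after PBS, 2 and 11 after LPS and 0 lists in the interaction; 757 of 758 and 1221 of 1221 calls were kept.

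Fixed-width windows around summits gave 0 lists in AF9 and in the interaction. Overlap of at least 50% gave 129 and 3 in naive, 273 and 32 in AF9, 0 lists in AF9 and in the interaction, and r = 0.579. No filter on the number of lists gave 1 list higher and 1 lower in naive. Chromosome X included gave 1 list lower in naive. Gene ends only gave 2 lists higher in AF9 and 0 in the interaction. A log rank changed no count by over 1.5 times.

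Presence in the equal-length lists gave 451 lower in naive, 270 higher in AF9, 57 and 28 after PBS, 30 and 13 after LPS, and 2 and 2 in the interaction with 0 lists. Presence in full lists with list length as covariate gave 0 and 0 in naive and AF9, 0 lower after LPS, 0 lists in AF9 and in the interaction, and r = 0.504. There Xrcc4 and Erg in naive reversed to -0.0327, Pbx3, Nmi, Cdk6, Mki67, Nos2 and Slc17a4 in AF9 to -0.0230, Mecom in AF9 to 0.206 and the neutrophil interaction to -0.0840. Presence at a -log10 q of at least 5 gave 3 and 0 in naive, 4 and 0 in AF9, 1 and 0 after LPS and 1 higher in the interaction, 0 lists in AF9 and in the interaction, and r = 0.583. Clcf1 in naive and Mecom and Lef1 in AF9 reversed to 0.25 and the neutrophil interaction to -0.0553. Presence holds 0 or 1 per list, so a peak found in both treatments at different ranks shows no change. With full lists, the Jaccard difference in AF9 was 0.0393 and no longer passed.

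List length as covariate gave 509 lower in naive, 749 lower in AF9 and 0 lists in the interaction. The replicate number as a block gave 344 and 161 in naive, 622 and 268 in AF9, 0 lower after LPS, and 0 lists in AF9 and in the interaction; 492 of 758 and 789 of 1221 calls were kept. The numbers do not pair the libraries: residuals of libraries with the same number correlated at -0.215 to 0.231, and 3 of 16 libraries correlated best with their own number. A fit of both groups alone gave 163 and 85 in naive and 0 lower after LPS. Median fold as covariate gave 445 lower in naive and 0 lists in AF9 and in the interaction.

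With Y peaks as covariate naive had 136 and 15, with 0 lower after LPS between backgrounds, 1 list lower there, 2 lists higher in naive and 0 in the interaction. Without libraries with Y peaks AF9 had 246 lower. With only AF9-experienced LPS libraries that have them, AF9 had 462 and 197 and 0 lists, with 0 lower and 1 list lower after LPS between backgrounds and 0 lists in the interaction.

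Leaving out 1 library, regions in naive ranged from 234 to 560 higher and from 109 to 572 lower, and in AF9 from 435 to 1004 higher and from 162 to 640 lower. Between backgrounds they were 0 after PBS, and 0 to 3 higher and 0 to 9 lower after LPS; lists were 0 to 1 lower after PBS, 0 to 1 lower in naive, 0 to 1 higher in AF9 and 0 to 1 higher in the interaction. The correlation of both LPS effects was 0.614 to 0.724. The Jaccard difference was -0.0198 to 0.00867 after PBS, -0.0135 to 0.0200 after LPS, 0.0335 to 0.0733 in naive and 0.0568 to 0.0631 in AF9. Peak number differences were -2072 to 26911 after PBS, -1845 to 16952 after LPS, -13459 to 10627 in naive and -18129 to 2915 in AF9, and gene-end share differences in percent -0.983 to -0.435, -2.06 to -0.184, -1.59 to 0.280 and -1.47 to -0.666.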

Other observations

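Chosen only after the result was seen were the test of whether short lists widen the spread, the count of full-list regions, the test of percentile ranks in LPS libraries with Y peaks, the Y peak covariate, and the genes named in the next paragraph. All other tests here were set before their result was seen.

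Some regions were among the 19100 strongest peaks of every library of a treatment and of none of the other. In the equal-length lists, 141 regions had a peak in all 8 LPS libraries and in no PBS library. Of the 141, 127 lay within 50 kb of a gene, and 6 of these (4.72%) were linked to a member of any gene list, against 2.71% of all merged regions so linked; this was not tested. Those with the highest mean percentile were nearest to Myo1d (56.4), Ltbp1 (54.6), Tent5c (52.2), Ptpn3 (51.7) and Ceacam19 (49.2). In the other direction, 29 regions had a peak in all 8 PBS libraries and in no LPS library; of those near a gene, the highest were nearest to Clcf1 (49.3), Zyx (44.4), Tcof1 (42.8) and Gsg1 (41.1). Of the 12870 splits of the 16 libraries into 8 and 8, 1 gave as many as 141 (the next highest 29) and 2 gave as many as 29 (the other being the LPS side, 141), so chance can be excluded for both. In the full lists 10 regions were in LPS libraries alone (77 of 12870 splits gave as many, highest other 366) and 0 in PBS libraries alone. None of these 10 was among the 141. The pattern of the 141 and of the 29 regions thus rests on the cut at 19100 peaks.

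Other splits of the libraries show where chance is unlikely. For LPS in naive mice 1 of 35 splits, the real one, gave as many called regions (758, highest other 436, naive PBS 2 to 4 against the rest). With 35 splits no smaller share is possible, so chance is unlikely there but not excluded. In AF9-experienced mice 1 of 100 splits, the real one, did (1221, highest other 373). With 100 splits no smaller share is possible either, so chance is unlikely there too but not excluded. The same holds for the correlation of both LPS effects (1 of 100 splits; 0.690 against 0.580). It does not hold for the NF-kB list in AF9-experienced mice, where 7 of 100 splits gave a camera p as small (0.00171; lowest of the others 5.3e-05). For AF9-experienced against naive after PBS and for the interaction the real count was 0, which every split reaches (35 of 35, highest other 1; 100 of 100, highest other 2), so these splits decide nothing.

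Calls between AF9-experienced and naive libraries after PBS appeared only with some settings. With library weights, 5 of 35 splits gave as many called regions (28; highest other 81), and with presence values 17 of 35 (85; highest other 299), so chance cannot be excluded for either count. Whether short lists widen the spread and so hide such regions cannot be told apart: without the 3 short lists the count was also 0, but at the 28 regions the median difference went from 14.0 to 19.1 (19.0 with weights), while the median SE went from 4.83 to 4.72 (3.59 with weights), with fewer libraries left. Without the short lists, at 59609 peaks per list and with library weights, 92 regions were called higher and 47 lower. A lasting mark of MLL-AF9 exposure is not shown by these calls and not excluded by their absence.

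The 3 regions lower in AF9-experienced than naive libraries after LPS, inside Rnf180, Fyb and Akap13, did not exceed chance: 11 of 56 splits gave as many (3). The highest other split, 137 regions, parts exactly the 5 LPS libraries with Y peaks from the 3 without, which points to a structure of the samples. At these regions the AF9-experienced LPS libraries with Y peaks stood at 0 to 4.18 and naive LPS at 19.1 to 43.9, apart by more than the naive SD at each. A bound set before, no peak in either AF9-experienced LPS library with Y peaks, was missed by 1 peak. The regions were called because AF9-experienced LPS libraries were low there, so these values cannot decide whether the batch or sex marked by Y peaks is the whole cause. With Y peaks as covariate the differences were -30.0 (SE 5.04), -26.2 (SE 4.77) and -29.3 (SE 5.92) against -29.1 (4.18), -26.9 (3.98) and -29.3 (4.78) before, and the calls ended with the wider error (adjusted p = 0.0876, 0.0876 and 0.132). One candidate explanation is that the regions fell below the list length, and all 15 pairs of a region and an AF9-experienced LPS library had a peak in the full lists. A difference between the backgrounds stays open.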
